A study of Arabidopsis thaliana with 87 samples.

How the data were processed

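Leaves of 4-week-old Arabidopsis plants grown at 22 °C with 18 h of light and 6 h of dark were sampled by the authors, RNA was extracted with TRIzol, and size-enriched small RNA was made into libraries with the TruSeq Small RNA kit. The 87 libraries were grouped by promoter, genotype and the leaf colour in their labels into 10 groups. The labels name 16 transgenic events, of which 11 carried 35S RUBY in Col-0, 2 carried it in dcl1234 and 3 carried ZmUBQ RUBY. The submitters' processing notes name the TAIR10 genome build. The aligner, adapter trimming, treatment of reads with several matches and read filters were not given in the sources used here, and neither was the set of sequences behind the mapped total.

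Each file gave, for the whole transgene, the read count that the authors assigned to each length from 18 to 28 nt and each strand, without normalization. The deposited RPM values were made by the authors as that count divided by the mapped reads of the library and multiplied by 1000000. This was checked on all lines, and 0 deviated by more than a relative tolerance of 1e-06. Length and strand combinations with no read were left out by the authors in 4 files, where they were set to 0, so that every library had 22 values. The files split the reads by length and strand and not by part of the transgene, and endogenous small RNAs were not analysed here. Mapped reads ranged from 0.905 to 31.4 M (1 M is 1000000 reads), 6 libraries had fewer than 8 M, and a count of 3 reads corresponded to 0.0955 to 3.32 RPM. Shares of reads within 1 library carry Wilson intervals at 95% confidence.

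Totals, 21 nt, 22 nt and 24 nt classes and strands were summed in RPM, a pseudocount of 1 RPM was added and log2 was taken. Shares were percentages of all 18 to 28 nt reads in libraries with at least 10 RPM, which all 87 reached. Before the data were examined, 12 comparisons of the total, 36 tests of length classes, 36 tests of their shares and 15 tests of strands were fixed, together with the groups, the alternatives and the named features. The named features were the total, the 21, 22 and 24 nt classes, the sum of 21 and 22 nt, all other lengths, and each strand. Each test was a two-sided permutation test of the difference in group means, exact where a group had fewer than 10 libraries and otherwise with 100000 resamples and a fixed seed, for which 1e-05 is the smallest p it can give. Benjamini-Hochberg adjustment was made within each of these families, and adjusted p under 0.05 counted as past the threshold. Intervals hold the shifts that the same test did not reject at 0.05. Another 36 tests, of lengths other than 21 to 24 nt, the minus strand and its share, were adjusted among themselves. Their features were among those named in advance, but the tests were chosen after seeing the data. Of these, 10 repeated strand tests of the fixed list, and 16 of the remaining 26 passed.

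Libraries with the same event and label number were treated as pairs, and sign-flip permutation of the differences within pairs was run as an alternative. Its adjustment ran only over tests that pairs allow: 5 of totals, 15 of length classes, 15 of shares and 15 of strands. Paired adjusted p-values for totals, length classes and shares therefore carry a correction for fewer tests than the unpaired ones. The pairing was checked by correlating totals over pairs in 7 relations and by correlating the length and strand profiles of pair members after group means were removed. Fully green leaves and green parts had a positive profile correlation above 0.1 in 9 of 9 pairs, the lowest at 0.32, which was not so in all pairs of the other relations. The promoter difference was tested by exchanging promoter labels over the pairs, and event differences by permuting event labels over libraries of events with at least 2 libraries.

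Alternatives fixed in advance were pseudocounts of 0.1 and 10 RPM, values under 1 RPM set to 0, ranks in place of log2 values, and 1 mean per event. Also fixed were sums over 21 to 24 nt or 21 and 22 nt only, shares of 21 to 24 nt reads, and minimum totals of 1 and 100 RPM. Further ones were the sum of 21 to 24 nt relative to all other lengths in place of the total, pairs, and leaving out each library and each event. Choices added after seeing the data were libraries under 8 M mapped reads left out, red parts of MK016 number 5 and MK025 number 1 left out, the minus strand only, and averaging of libraries that a test did not separate from sampling noise. The last came from a check of all 402 pairs of libraries within groups, in which a chi-squared test on their length and strand counts and all other mapped reads gave p over 0.05 for 3 pairs. The permutation test was tested on simulated data with the depths and pooled spread of each comparison, 200 times per setting. Every library was drawn independently, with the same spread in both groups and no event effect. The simulation therefore does not cover groups of unequal spread or several libraries of 1 event. With no true difference it gave p under 0.05 in 2 to 7% of simulations, with a true fold of 2 in 28 to 99.5%, and with a true fold of 4 in 88.5 to 100%. The mean estimate was off by at most 0.05 on the log2 scale. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.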

Results

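Small RNA was sequenced from 4-week-old Arabidopsis leaves that carried RUBY, a transgene whose enzymes make the red pigment betalain, so that leaf colour reports whether the transgene is active. The 87 libraries came from 16 transgenic events. RUBY was driven by the 35S promoter of cauliflower mosaic virus in 69 libraries and by ZmUBQ, named after a maize ubiquitin promoter, in 18 libraries. In Col-0, the wild-type background, the 35S libraries comprised 9 of fully green leaves, 13 of fully red leaves, 13 of green parts and 13 of red parts of leaves, 11 of always red plants and 2 of always green plants. Another 8 always red 35S libraries came from dcl1234, a line mutated in the DICER-LIKE genes that cut RNA into small RNAs. The ZmUBQ libraries, all in Col-0, comprised 7 of fully green leaves, 7 of fully red leaves and 4 of always red plants. Each library was described by its reads on the whole transgene, by length from 18 to 28 nt and by strand, as reads per 1000000 mapped reads (RPM). Total mapped reads ranged from 0.905 to 31.4 M (1 M is 1000000 reads) per library, with a median of 15.4 M mapped reads, and reads on the transgene ranged from 404 to 2005605. The median was 12.8 M for 35S fully green, 16.8 M for fully red, 17.5 M for green parts, 17.3 M for red parts, 19.1 M for always red, 20.3 M for always green and 15.2 M for dcl1234. For ZmUBQ it was 13.1 M in fully green, 12.9 M in fully red and 16.0 M in always red libraries. A count of 3 reads corresponded to between 0.0955 and 3.32 RPM, with a median of 0.195 RPM. That floor and the intervals for shares within 1 library cover counting error only, because PCR reads without molecular identifiers are not independent molecules. Folds are ratios of geometric means, differences are on the log2 scale unless given in percentage points, and all tests are two-sided permutation tests, exact where a group has fewer than 10 libraries. Their p-values measure the spread between these libraries, of which several can come from 1 event, and libraries of 1 event are not independent insertions.

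**Figure D1:**
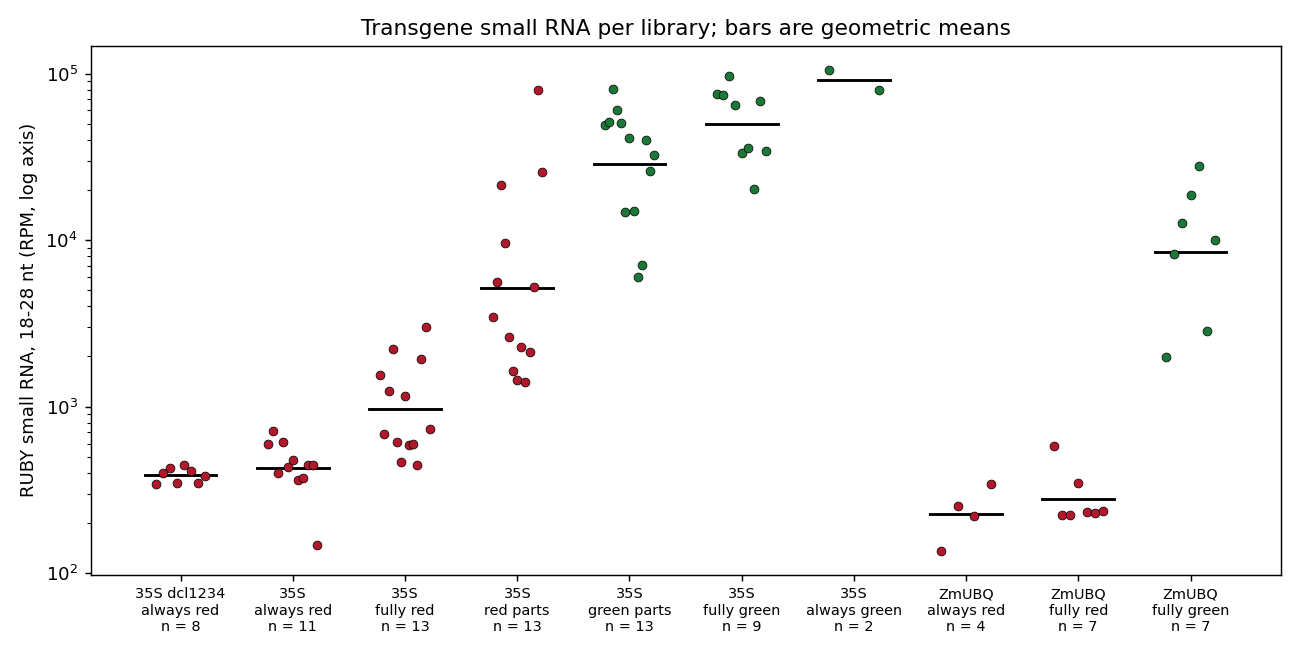
RUBY small RNA of 18 to 28 nt per library (RPM, log axis) in the 10 groups, with 1 point per library and a bar at the geometric mean. The 9 fully green 35S libraries lay between 20371 and 97070 RPM and the 13 fully red ones between 446 and 2989 RPM.

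The contrast of fully green with fully red leaves asks how much small RNA marks leaves that lost the red pigment under the 35S promoter. Transgene small RNA reached 55928 ± 25675 RPM (SD, n = 9) in fully green leaves and 1172 ± 795 RPM (SD, n = 13) in fully red leaves. Small RNAs of 21 nt made up most of the green signal, at 43699 ± 20019 RPM, against 686 ± 591 RPM in red leaves, and the 22 nt class held 6053 ± 2802 and 121 ± 80.0 RPM. The 24 nt class was smaller, at 1273 ± 653 and 44.8 ± 15.7 RPM. Together, 21 and 22 nt reads reached 49752 ± 22817 RPM in green and 806 ± 671 RPM in red leaves, and the remaining lengths other than 21 to 24 nt reached 4360 ± 2595 and 289 ± 120 RPM. The total was 51.8-fold higher in fully green leaves (95% interval 30.3 to 88.2; exact permutation p = 2.01e-06, adjusted p = 2.41e-05). All 9 green libraries exceeded all 13 red ones, and the green member was higher in 9 of 9 pairs of the same event and number. Within these pairs the fold was lower, at 41.7 (sign-flip permutation, adjusted p = 0.00651). The rise was 81.8-fold for 21 nt, 53.2-fold for 22 nt and 25.6-fold for 24 nt small RNA, each with adjusted p = 2.41e-05 and with all 9 green libraries above all red ones. Within the 9 pairs it was 61.3-fold, 43.8-fold and 23.1-fold. Both strands enter these folds. On the minus strand, mean 24 nt reads were 10.7 RPM in red and 691 RPM in green leaves, and 21 nt reads 405 and 25859 RPM. On the plus strand the means were 34.1 and 582 RPM at 24 nt, and 281 and 17840 RPM at 21 nt. In these means, the smaller 24 nt rise lay on the plus strand.

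The length and strand make-up of all transgene reads differed as well. In fully red leaves, mean plus strand reads lay between 22.0 and 45.1 RPM at every length other than 21 and 22 nt. Shares of all reads weigh such a part more where the total is low. Within the minus strand, length ratios were close between the colours, although no test was made of them. The median ratio of 22 to 21 nt reads there was 11.7% in green and 11.9% in red leaves. For 24 to 21 nt reads the medians were 2.69% and 2.68%. Red libraries spread more widely, from 11.2 to 33.3% and from 0 to 3.14%. Of 21 nt reads alone, the minus strand held 60.2 ± 4.75% in green and 54.6 ± 11.1% in red leaves. Small RNAs of 21 nt held 78.2 ± 2.31% of transgene small RNA in fully green leaves and 51.9 ± 14.7% in fully red leaves (exact permutation, adjusted p = 0.000275), and all 9 green libraries were above all red ones. The 24 nt share was 2.22% in green and 4.84% in red leaves (adjusted p = 0.00458), with 5 of 9 green libraries below all red ones. For 22 nt the shares were 10.8% and 10.4%, a difference inside the spread between libraries (adjusted p = 0.131), although it passed in the 9 pairs (0.60 percentage points, adjusted p = 0.0304). As a share of 21 to 24 nt reads the direction turned and the difference passed over all libraries (-3.36 points, adjusted p = 0.00219). Reads on the minus strand, as the files name the strands of the transgene sequence, rose 87.1-fold and those on the plus strand 35.6-fold (both adjusted p = 1.51e-05, all 9 green libraries above all red ones). The minus strand held 58.8 ± 4.47% of reads in green and 38.9 ± 14.7% in red leaves (adjusted p = 0.00105, 8 of 9 pairs higher in green). Which strand matches the RUBY messenger RNA was not given in the sources used here. The fully red library of MK044 number 3 had only 0.905 M mapped reads and 404 transgene reads, and its 21 nt share of 19.1% carried a 95% Wilson interval of 15.5 to 23.2%.

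**Figure D2:**
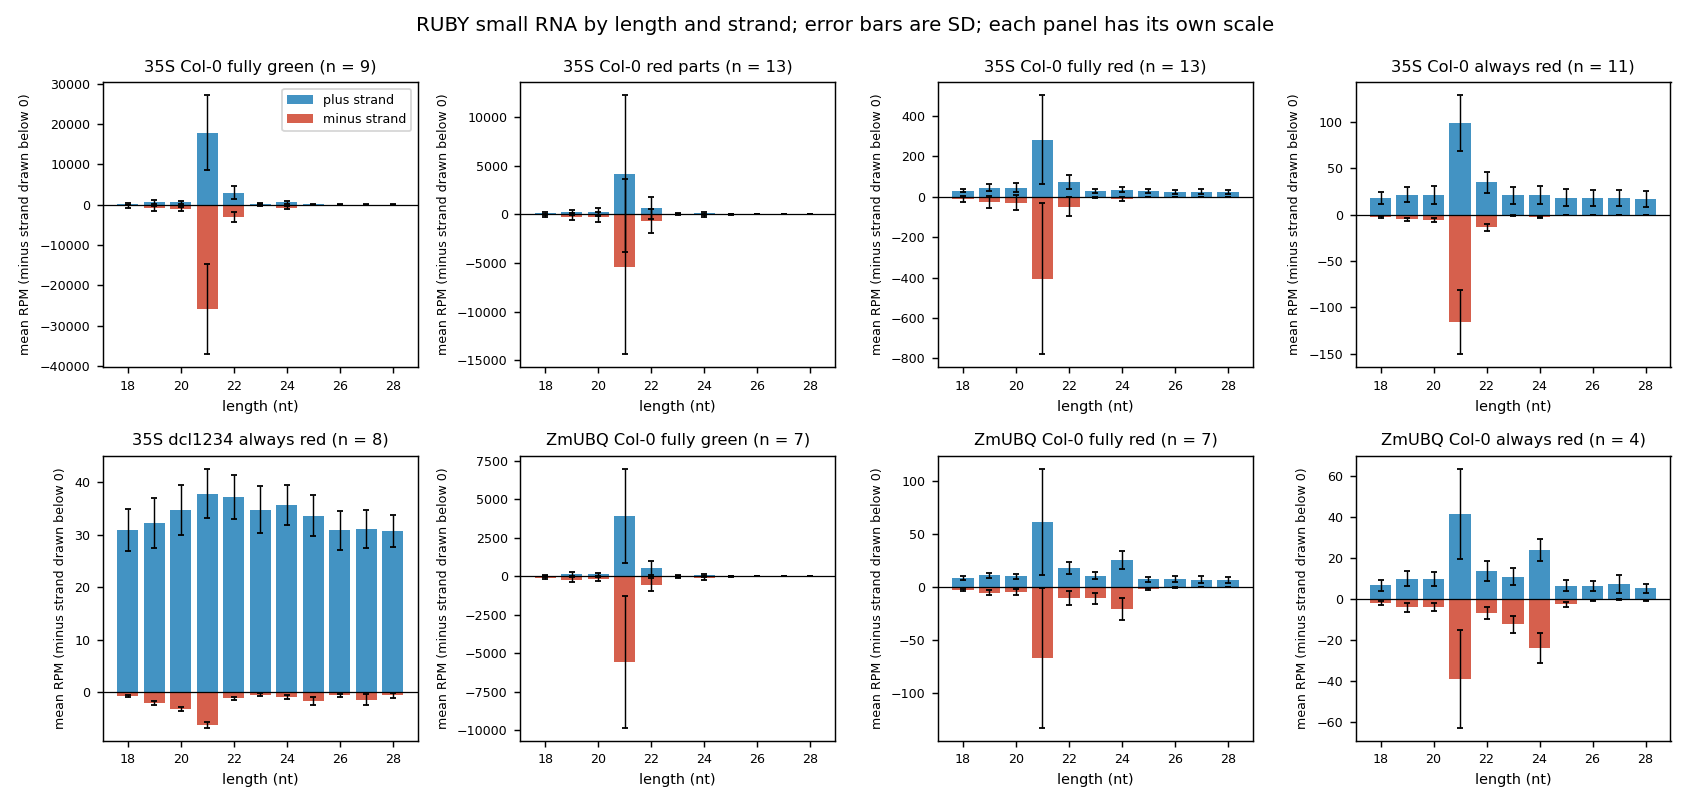
Mean RUBY small RNA (RPM) at each length from 18 to 28 nt, plus strand above 0 and minus strand below 0, in 8 groups with SD bars and a separate scale per panel. The 21 nt class was the tallest on both strands in every panel of Col-0, with a mean of 43699 RPM over both strands in fully green 35S leaves and 44.0 RPM in dcl1234.

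The labels also name green parts and red parts, read here as the sectors of leaves of mixed colour, so that both colours can be compared within such leaves. Green parts carried 36562 ± 22390 RPM (SD, n = 13) and red parts 12444 ± 21537 RPM (SD, n = 13), with a median of 3470 RPM in red parts. Green parts contained 28340 ± 17427 RPM of 21 nt small RNA and red parts 9558 ± 16974 RPM, and the 24 nt class stood at 699 ± 497 and 185 ± 278 RPM. Green parts exceeded red parts in 12 of 13 pairs. The exception was MK016 number 5, whose red parts reached 79188 RPM against 26078 RPM in its green parts. The total was 5.54-fold higher in green parts (95% interval 2.33 to 13.1; permutation p = 0.00092, adjusted p = 0.00184). The 21, 22 and 24 nt classes were 5.90-fold, 5.42-fold and 5.47-fold higher (adjusted p = 0.00211, 0.00254 and 0.00175). The plus strand rose 5.08-fold and the minus strand 5.88-fold (adjusted p = 0.00199 and 0.00105). The 21 nt share was 77.3 ± 3.42% in green and 72.6 ± 4.95% in red parts (adjusted p = 0.0255), and the 24 nt share did not differ beyond the spread (1.85% and 1.90%, adjusted p = 0.785).

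The minus strand share was 60.3 ± 3.62% in green parts and 56.7 ± 3.69% in red parts (adjusted p = 0.0276, higher in 9 of 13 pairs). That call ended without red parts of MK043 number 2 (2.99 percentage points, adjusted p = 0.0520) or of MK044 number 3 (3.09 percentage points, adjusted p = 0.0505). Adjusted among the 36 tests chosen after seeing the data, the same difference lost its call in 11 of 26 cases with 1 library left out, and in pairs (exact permutation, adjusted p = 0.0505). The 4 leaf-part libraries under 8 M mapped reads, 3 of them red parts, had 52.7 ± 1.48% of their 21 nt reads on the minus strand, against 63.1 ± 2.59% in the other 22. Red parts of MK016 number 5 and MK025 number 1 held 79188 and 25783 RPM, the highest values of their group, at 7.98 and 4.95 M mapped reads. Without both, green parts stood 8.22-fold above red parts (adjusted p = 0.0003). The sum of 21 to 24 nt relative to the other lengths of the same library was 1.48-fold higher in green parts and fell short of the threshold (adjusted p = 0.0670). Those other lengths were themselves higher in green parts, so this ratio does not measure the level.

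Red parts were also compared with fully red leaves, which asks whether red parts, as labelled, resemble wholly red leaves. How free the red parts were of green tissue was not tested, so a higher level in them cannot be assigned to red tissue alone. Red parts held more transgene small RNA, at 12444 RPM against 1172 RPM on average and at medians of 3470 and 734 RPM. More of it was 21 nt long, at 72.6 ± 4.95% against 51.9 ± 14.7%. The red parts library was higher in 13 of 13 pairs of the same event and number, and 7 of 13 red parts libraries exceeded every fully red library. The total was 5.32-fold higher in red parts (95% interval 2.40 to 12.0; permutation p = 0.0001, adjusted p = 0.0006). The 21 nt class rose 7.79-fold (adjusted p = 0.000288), the 22 nt class 5.33-fold (adjusted p = 0.00042) and the 24 nt class 2.21-fold (adjusted p = 0.0253). Reads on the minus strand rose 8.65-fold and on the plus strand 3.85-fold (adjusted p = 0.000187 and 0.00081). The minus strand share rose by 17.8 percentage points (adjusted p = 0.000187, 12 of 13 pairs), the 21 nt share by 20.7 points and the 24 nt share fell by 2.94 points (both adjusted p = 0.000119). Plus strand reads of 25 and 28 nt averaged 27.2 and 18.7 RPM in red parts. In fully red leaves they averaged 26.4 and 22.0 RPM, a larger part of a lower total. Mean 21 nt reads on the minus and plus strands were 5376 and 4182 RPM in red parts. The same means were 405 and 281 RPM in fully red leaves. In these means the minus strand share of 21 nt reads was not higher in red parts. Without red parts of MK016 number 5 and MK025 number 1, the total was 3.58-fold higher (adjusted p = 0.00081) and the 24 nt class 1.6-fold higher, no longer past the threshold (adjusted p = 0.0901). On ranks, the 24 nt class also missed it (adjusted p = 0.0559).

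**Figure D3:**
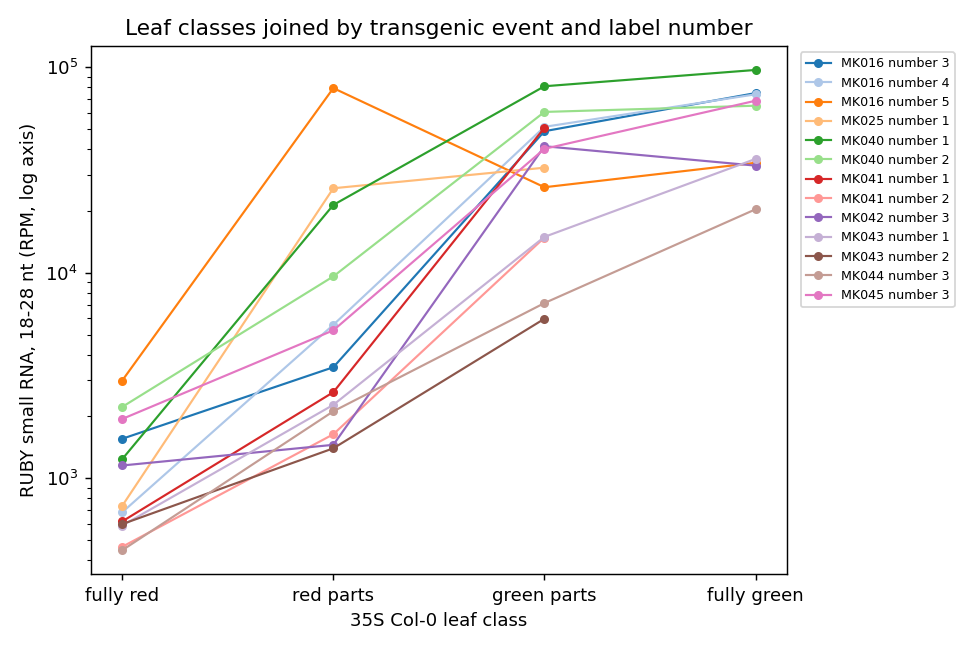
RUBY small RNA per 35S Col-0 library (RPM, log axis) by leaf class, with a line joining libraries of the same event and label number. Red parts lay above fully red leaves in 13 of 13 pairs and green parts above red parts in 12 of 13, the exception being MK016 number 5 (79188 RPM in red parts, 26078 RPM in green parts).

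The comparison of fully green leaves with green parts asks whether green sectors reach the level of wholly green leaves. Fully green leaves held 55928 RPM and green parts 36562 RPM, with 21 nt shares of 78.2% and 77.3% (adjusted p = 0.529), a difference that turned and passed as a share of 21 to 24 nt reads (-0.762 points, adjusted p = 0.0256). Across all libraries the total was 1.76-fold higher in fully green leaves, a difference within the spread (95% interval 0.921 to 3.37; exact permutation p = 0.0848, adjusted p = 0.113). Within the 9 pairs of the same event and number it was 0.57 higher on the log2 scale and passed (exact permutation, adjusted p = 0.0156, 8 of 9 pairs). The 21 and 22 nt classes were 1.78-fold and 1.84-fold higher, without passing over all libraries (adjusted p = 0.0996 and 0.0875), and both passed in pairs (adjusted p = 0.0167 each). The 24 nt class was 2.12-fold higher over all libraries (adjusted p = 0.0466) and higher in 9 of 9 pairs (adjusted p = 0.00651). Leaving out 1 library ended that 24 nt call in 13 of 22 cases, with log2 differences of 0.90 to 1.27 and adjusted p of 0.0215 to 0.0948, and it also missed the threshold on ranks (adjusted p = 0.0559) and without libraries under 8 M mapped reads (1.03, adjusted p = 0.0881). The 24 nt share was 0.373 percentage points higher in fully green leaves (adjusted p = 0.0111, 3 of 9 above all green parts), and the 22 nt share passed in pairs only (10.8% and 10.3%, adjusted p = 0.131 unpaired and 0.0234 paired). The minus strand share was 58.8% in fully green leaves and 60.3% in green parts, a difference that passed only in the pairs, where 1 of 9 was higher in fully green leaves (adjusted p = 0.393 unpaired and 0.0176 paired). Reads on the plus and minus strands were 1.82-fold and 1.71-fold higher (adjusted p = 0.0943 and 0.0966), and both passed in pairs (adjusted p = 0.0176 and 0.0293). Without fully green MK044 number 3, the 22 nt class (1.06 on the log2 scale, adjusted p = 0.0403) and both strands (1.03 and 0.93, adjusted p = 0.0495 each) passed over all libraries, and the 22 nt class also passed without green parts of MK040 number 1 (adjusted p = 0.0454).

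Always red plants serve as the reference for fully red leaves, each of which shares its event and number with a library of green parts. Of the 6 always red events, 4 also gave fully red leaves. Always red plants held 456 ± 151 RPM (SD, n = 11) and fully red leaves 1172 ± 795 RPM (SD, n = 13). Always red plants held 214 ± 64.2 RPM of 21 nt small RNA against 686 ± 591 RPM, the 22 nt class 48.3 ± 14.9 against 121 ± 80.0 RPM, and the 24 nt class 24.3 ± 10.5 against 44.8 ± 15.7 RPM. Fully red leaves held 2.26-fold more in total (95% interval 1.43 to 3.60; permutation p = 0.00084, adjusted p = 0.00184), and 7 of 13 exceeded every always red library. In 8 of the 11 always red libraries the ratios of 22 and 24 nt to 21 nt reads on the minus strand lay within the range of the 22 green libraries. The 21, 22 and 24 nt classes were 2.36-fold, 2.18-fold and 1.86-fold higher (adjusted p = 0.0141, 0.00208 and 0.00208). The shares of 21, 22 and 24 nt did not differ beyond the spread (adjusted p = 0.468, 0.218 and 0.709), except that the 22 nt share passed without always red MK010 number 1 (-0.442 percentage points, adjusted p = 0.0318). Lengths other than 21 to 24 nt, a test chosen after seeing the data, rose 1.98-fold (adjusted p = 0.00195). The sum of 21 to 24 nt relative to those lengths was 1.17-fold higher and did not pass (adjusted p = 0.412). With 1 value per event, the total still passed (2.12-fold, adjusted p = 0.0464) and the 21 nt class did not (adjusted p = 0.18).

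Always green plants came from 1 event, MK017, with 2 libraries of 79466 and 105085 RPM. These values were 214-fold above always red plants as a ratio of geometric means (95% interval 94.1 to 404), and both exceeded all 11 always red libraries. The 21, 22 and 24 nt classes were 337-fold, 201-fold and 93.4-fold higher, and the 21 nt share was 74.9% against 47.6%. The exact permutation p for the total was 0.0128, the smallest that 2 against 11 libraries can give, with adjusted p = 0.022, and adjusted p was 0.0185 for each length class. With only 1 always green library left, or with 1 value per event, no test could pass. Against fully green leaves the always green libraries were 1.82-fold higher, within the spread (95% interval 0.667 to 4.20; exact permutation p = 0.109, adjusted p = 0.131). The 21, 22 and 24 nt classes were 1.74-fold, 1.74-fold and 1.96-fold higher without passing (adjusted p = 0.205, 0.169 and 0.131). For the sum of 21 to 24 nt relative to the other lengths, the difference turned to -0.60 on the log2 scale (adjusted p = 0.218).

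The dcl1234 line asks how much of the transgene small RNA of always red plants depends on DICER-LIKE enzymes. Its libraries held 44.0 ± 4.83 RPM (SD, n = 8) of 21 nt small RNA against 214 ± 64.2 RPM (SD, n = 11) in always red Col-0. The 22 nt class stood at 38.3 ± 4.28 and 48.3 ± 14.9 RPM, and the 24 nt class at 36.5 ± 3.80 and 24.3 ± 10.5 RPM. Only 11.3% of the reads were 21 nt long in dcl1234, against 47.6 ± 5.15% in Col-0, and the minus strand held 4.89 ± 1.17% against 32.6 ± 4.30%. The 21 nt class was 4.53-fold lower in dcl1234 (exact permutation, adjusted p = 0.000119) and all 8 dcl1234 libraries lay below all 11 of Col-0. The 24 nt class was 1.6-fold higher (adjusted p = 0.0131), while the 22 nt class was 1.19-fold lower within the spread (adjusted p = 0.253). That 22 nt sum joined strands that differed. Minus strand 22 nt reads stood at 1.15 ± 0.311 RPM in dcl1234 against 13.5 ± 3.76 RPM in Col-0. On the plus strand they were 37.2 ± 4.21 and 34.9 ± 11.7 RPM. The higher 24 nt level lay on the plus strand, at 35.6 ± 3.76 RPM in dcl1234 and 21.3 ± 10.1 RPM in Col-0, whereas 24 nt reads of the minus strand were lower in dcl1234, at 0.885 ± 0.410 RPM against 2.96 ± 0.837 RPM. It was not particular to 24 nt: plus strand reads of 25 and 28 nt stood at 33.6 and 30.7 RPM in dcl1234 and 18.5 and 17.0 RPM in Col-0. RPM is relative to mapped reads, and a change in what those reads contain in dcl1234 was not separated from a change in transgene reads. The 21 nt share fell by 36.2 percentage points and the 24 nt share rose by 4.15 points (both adjusted p = 0.000119, 8 of 8 libraries outside the Col-0 range), and the 22 nt share was 9.87% against 10.7% (adjusted p = 0.0147). That last difference depended on the denominator, since as a share of 21 to 24 nt reads the 22 nt class was 9.19 points higher in dcl1234 (adjusted p = 0.000119).

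In total the dcl1234 and Col-0 libraries differed by less than their spread, at 388 ± 39.6 and 456 ± 151 RPM (log2 difference -0.14, fold 0.906, 95% interval 0.682 to 1.24, exact permutation p = 0.569, adjusted p = 0.569). Without always red MK034 number 2, which held 147 RPM, the total was lower in dcl1234 (-0.30, adjusted p = 0.0410) and so was the 22 nt class (-0.40, adjusted p = 0.00342). The 22 nt class also passed on ranks (adjusted p = 0.0197). Limited to 21 to 24 nt, the difference was -0.92 on the log2 scale (adjusted p = 0.0018). Among tests chosen after seeing the data, reads on the minus strand were 7.12-fold lower in dcl1234 and their share fell by 27.7 percentage points (both adjusted p = 0.000119, 8 of 8 below all Col-0). Lengths other than 21 to 24 nt were 1.73-fold higher in dcl1234 (234 ± 23.8 against 147 ± 61.2 RPM, adjusted p = 0.00583). With 1 value per event, 2 dcl1234 events stood against 6 of Col-0, and the 21 nt difference was -2.19 on the log2 scale (adjusted p = 0.0804). So few events allow few splits, and no length class or length share of this comparison passed in that form. The dcl1234 events were other transformation events than those of Col-0, so genotype and event cannot be parted.

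**Figure D4:**
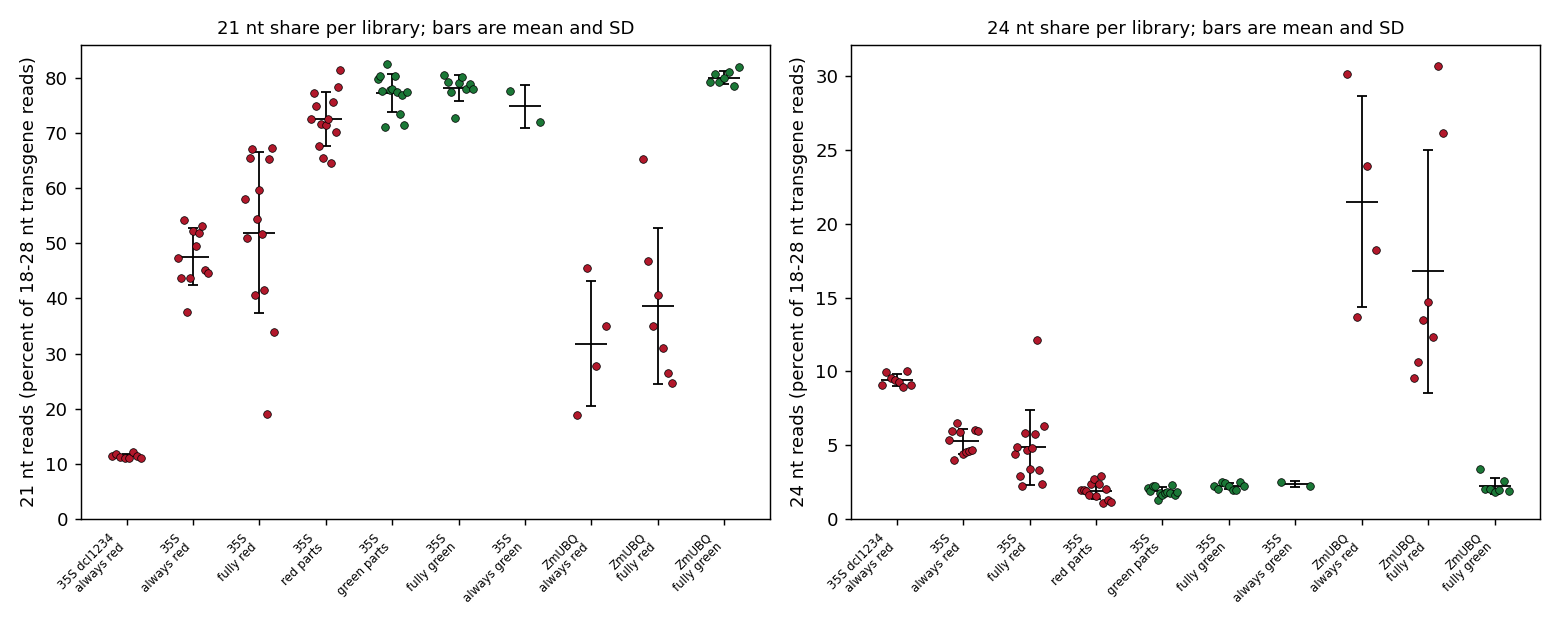
Share of 21 nt reads and of 24 nt reads among transgene reads of 18 to 28 nt (percent) per library in the 10 groups, with bars at the mean and SD. The mean 21 nt share was 78.2% in fully green 35S leaves, 47.6% in always red 35S Col-0 and 11.3% in dcl1234, and the mean 24 nt share reached 21.5% in always red ZmUBQ plants.

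Under the ZmUBQ promoter, the same contrast of green with red leaves was drawn in 3 events. Fully green leaves held 11752 ± 9090 RPM (SD, n = 7) and fully red leaves 297 ± 134 RPM (SD, n = 7). Small RNA of 21 nt reached 9455 ± 7352 RPM in green and 128 ± 115 RPM in red leaves, while the 22 nt class held 1091 ± 872 and 28.1 ± 11.5 RPM and the 24 nt class 233 ± 167 and 46.1 ± 18.5 RPM. The share of 24 nt reads was 16.8 ± 8.23% in red and 2.23% in green leaves. Green leaves held 30.3-fold more in total (95% interval 12.7 to 69.9; exact permutation p = 0.000583, adjusted p = 0.00175), with 7 of 7 green libraries above all red ones. The 21 nt class rose 65.7-fold, the 22 nt class 28-fold and the 24 nt class 4.25-fold (adjusted p = 0.00175, 0.00175 and 0.00254). The 21 nt share was 80.1 ± 1.2% in green and 38.6 ± 14.2% in red leaves, and both this and the 24 nt share passed (adjusted p = 0.00262, 7 of 7 libraries apart). Plus strand reads rose 21.3-fold and minus strand reads 44.6-fold, and the minus strand share was 57.7 ± 1.37% against 39.6 ± 7.61% (adjusted p = 0.00105 each). With 1 value per event, 3 events against 3 cannot give an exact permutation p under 0.1, and none of these tests could pass.

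Fully red leaves of ZmUBQ events and always red ZmUBQ plants, at 297 ± 134 RPM (SD, n = 7) and 238 ± 85.5 RPM (SD, n = 4), did not differ beyond the spread. The total was 1.23-fold higher in fully red leaves (95% interval 0.735 to 2.10; exact permutation p = 0.388, adjusted p = 0.423), and its direction turned without event MK054 (-0.13). The 21, 22 and 24 nt classes gave folds of 1.48, 1.36 and 0.920 (adjusted p = 0.408, 0.253 and 0.721), and the 24 nt direction turned without fully red MK054 number 4 or always red MK056 number 4 (0.01 and 0.02 on the log2 scale).

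Between promoters, fully green leaves held less transgene small RNA under ZmUBQ, at 11752 RPM against 55928 RPM under 35S. The total was 5.93-fold lower (95% interval 2.68 to 13.2; exact permutation p = 0.000175, adjusted p = 0.000699), and 6 of 7 ZmUBQ libraries lay below all 9 of 35S. The 21, 22 and 24 nt classes were 5.79-fold, 6.98-fold and 5.98-fold lower (adjusted p = 0.000699 each). The 22 nt share was 9.13% against 10.8% (adjusted p = 0.00105, 7 of 7 below all 35S libraries), a call that ended with 1 value per event. The 21 and 24 nt shares did not pass (adjusted p = 0.0997 and 0.976), except for the 21 nt share without fully green MK016 number 3 of 35S (2.15 percentage points, adjusted p = 0.0404) and as a share of 21 to 24 nt reads (1.83 points, adjusted p = 0.00157). Lengths other than 21 to 24 nt fell alongside, so that the sum of 21 to 24 nt relative to them differed by -0.01 on the log2 scale (adjusted p = 0.978). The 2 constructs are different mapping targets, and reads of other origin that match either one were not separated here. Promoter and submission batch also coincide. This and the following comparisons between promoters therefore describe these libraries and cannot part the 2.

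In always red plants the length make-up of transgene small RNA differed between promoters. ZmUBQ plants held 47.7 ± 12.3 RPM (SD, n = 4) of 24 nt small RNA against 24.3 ± 10.5 RPM (SD, n = 11) under 35S, and 80.6 ± 45.5 against 214 ± 64.2 RPM of 21 nt small RNA. The 24 nt share was 21.5 ± 7.14% under ZmUBQ and 5.26 ± 0.844% under 35S, with 4 of 4 ZmUBQ libraries above all 11 of 35S (exact permutation, adjusted p = 0.00293). The 24 nt class was 2.04-fold higher (adjusted p = 0.0156), and this call ended without always red ZmUBQ MK056 number 2 (0.98, adjusted p = 0.0513) or number 4 (0.89, adjusted p = 0.0513). The 21 nt class was 2.92-fold lower (adjusted p = 0.00972) and the 22 nt class 2.29-fold lower (adjusted p = 0.00733). The 21 and 22 nt shares were lower as well, at 31.8% and 8.56% against 47.6% and 10.7% (adjusted p = 0.0122 and 0.0048). The total was 1.88-fold lower under ZmUBQ (95% interval 1.14 to 3.18; exact permutation p = 0.0176, adjusted p = 0.0264). That call ended without always red ZmUBQ MK054 number 1 (-0.67, adjusted p = 0.114) and with 1 value per event (-0.96, adjusted p = 0.184). The direction turned for the sum of 21 to 24 nt relative to the other lengths (0.25, adjusted p = 0.218). With 1 value per event, 2 ZmUBQ events stood against 6 of 35S, and no length class or length share of this comparison passed either.

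The rise from fully red to fully green leaves did not differ detectably between promoters. It averaged 4.92 ± 1.70 on the log2 scale in 7 ZmUBQ pairs and 5.38 ± 0.94 in 9 pairs of 35S (difference -0.46, 95% interval -1.90 to 0.92, exact permutation p = 0.516). The fold within a pair ranged from 3.42 in MK054 number 3 to 119 under ZmUBQ, and from 11.5 in MK016 number 5 to 108 in MK016 number 4 under 35S. Without ZmUBQ MK054 number 3 the difference turned to 0.06.

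A difference between events was not shown in any of 5 colour classes of 35S Col-0 leaves. Event accounted for 67.3% of the variance in always red plants, where 44.4% is the mean under permuted event labels (permutation p = 0.0347, adjusted p = 0.147), and for 74.4% in green parts, where that mean is 37.5% (permutation p = 0.0588, adjusted p = 0.147), and always red was the only class with an unadjusted p under the threshold of 0.05. Among tested events, green parts averaged 70750 RPM in MK040 and 10464 RPM in MK043, with 2 libraries each. Among 7 relations between leaf classes of the same event and number, fully green leaves and green parts moved together over 9 pairs (Pearson r = 0.88, permutation p = 0.000989, adjusted p = 0.00693). Spearman's rho was 0.75 (permutation p = 0.0255, adjusted p = 0.0892), and r was 0.79 without the 2 pairs farthest from the median. Red parts and fully red leaves had r = 0.62 over 13 pairs (permutation p = 0.0228, adjusted p = 0.0798) and r = 0.35 without the 2 farthest, with rho = 0.67 (permutation p = 0.0147, adjusted p = 0.0892). None of the other 5 relations passed after adjustment.

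Across all 12 comparisons, the total passed in 8, of which 6 were higher in the first-named group and 2 lower. The 3 length classes passed in 27 of 36 tests, 21 higher and 6 lower, their shares in 17 of 36, and the strands in 12 of 15, all 12 higher. Among 402 pairs of libraries within a group, a chi-squared test on counts by length and strand out of all mapped reads did not separate 3 from sampling noise at 0.05: fully red MK041 number 1 and MK043 number 2 of 35S (p = 0.187), always red MK042 number 1 and MK045 number 2 of 35S (p = 0.105), and dcl1234 MK072 number 2 and MK073 number 5 (p = 0.0690). They came from different events with different mapped totals and stayed separate libraries.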

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

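The gap test was fixed before the result was seen, and the tests of the 3 patterns that follow were chosen only after the results they measure were seen. Among 25 sets of libraries and measures, 1 library stood apart from its group: fully green MK040 number 2 of 35S had a 21 nt share of 72.7%, the nearest of the other 8 libraries was at 77.5%, and the gap took up 0.620 of the range. By chance about 1 of 20 sets passes the critical value of this test, so passing it in 1 of 25 sets is not unusual, but how often chance gives a gap of 0.620 was not computed. No biological explanation was tested for it.

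Always red 35S plants of Col-0 held 115 ± 34.7 RPM (SD, n = 11) of 21 nt reads on the minus strand, although their leaves were red. One candidate source is reads misassigned from green libraries sequenced alongside, which would carry the length ratios of green leaves: 8 of 11 always red libraries had 22 nt and 24 nt to 21 nt ratios on the minus strand within the range of the 22 green libraries. Small RNA made in red leaves by DICER-LIKE enzymes may also explain it, since the same reads stood at 6.19 ± 0.540 RPM (SD, n = 8) in dcl1234, 15.3-fold lower (95% interval 11.2 to 19.8, exact permutation p = 1.32e-05). Both stay open: the low value in dcl1234 bounds misassignment only if those libraries shared sequencing runs with green ones, which the labels do not give.

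Red ZmUBQ leaves held 24 nt reads on the minus strand at a level above red 35S leaves, 6.14-fold in always red plants (95% interval 4.45 to 8.42; exact permutation, adjusted p = 0.00147) and 2.41-fold in fully red leaves (95% interval 1.06 to 5.53; adjusted p = 0.0365). A 24 nt tail of the 21 nt small RNA of green leaves was argued against, because the lowest ratio of 24 to 21 nt reads in a red ZmUBQ library was 12.2%, above the highest ratio of 4.10% in fully green ZmUBQ leaves. RNA fragments of no set length were argued against too, because 24 nt reads were 9.78 times as frequent as 25 nt reads, and more than 2 times in 11 of 11 libraries. The shorter neighbour was closer: minus strand reads of 23 nt averaged 10.7 RPM in fully red and 12.2 RPM in always red ZmUBQ libraries, beside 20.6 and 23.6 RPM at 24 nt. Under 35S the 23 nt means were 3.34 and 0.903 RPM. Endogenous 24 nt reads that also map to the ZmUBQ construct could not be told apart from reads of the transgene: they would give each event the same level, and the events differed at p = 0.0450 (permutation), or 0.135 after correction for 3 tests. MK054 held 17.9 ± 7.00 RPM (SD, n = 4), MK055 14.8 ± 6.82 RPM (SD, n = 3) and MK056 30.6 ± 4.98 RPM (SD, n = 4). A biological difference between the promoters stays among the open explanations, untested. So does a difference between submission batches, which coincide with the promoters.

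Leaf-part libraries with fewer than 8 M mapped reads, a limit chosen after seeing the data (green parts of MK041 number 1 and red parts of MK025 number 1, MK044 number 3 and MK016 number 5), had 52.7 ± 1.48% (SD, n = 4) of their 21 nt reads on the minus strand, against 63.1 ± 2.59% (SD, n = 22) in the others, and 1.09 to 1.30% of 24 nt reads against 1.57 to 2.87%. Whether a low library yield shifts the strand balance could not be settled on the other 2 libraries under 8 M mapped reads: 1 of 2, fully red MK044 number 3, had a minus strand percentage of 21 nt reads below all others of its group (19.5% against 52.3 to 63.8%), while fully green MK045 number 3 lay within its group (55.4% against 52.5 to 66.2%). Both had the highest 24 nt share of their group, at 12.1% and 2.51%, opposite to the leaf parts, and MK044 number 3 had only 404 transgene reads. An exchange of the red and green parts of MK016 number 5 could not be excluded or shown: its green parts held 26078 RPM, just above the range of the other red parts (1399 to 25783 RPM, median 3047), and its red parts 79188 RPM. No biological explanation was tested.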

How the results depend on the processing

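Except where said otherwise these alternatives were fixed in advance; leaving out shallow or doubtful libraries, the minus strand alone and averaging were chosen after seeing the data. Depth was lowest in fully red MK044 number 3, with 404 transgene reads, which limits its shares. Fully green against fully red leaves of 35S kept its call in 43 of 43 alternatives (5.38 to 6.44, adjusted p 2.41e-05 to 0.00651), and red parts against fully red leaves in 47 of 47 (1.82 to 3.11, adjusted p 8e-05 to 0.00839). For all 12 totals, 215 of 219 values with 1 library left out kept direction and side of the threshold, 3 were weaker and 1 stronger; of 234 others, 214 did, 11 were weaker, 6 stronger and 3 turned direction. The 87 fixed tests of single lengths, shares and strands kept theirs in 1600 of 1644 values with 1 library left out, with 27 weaker, 7 stronger and 10 turned, and in 649 of 705 others, with 37, 12 and 7. Minimum totals of 1 and 100 RPM removed no library, since the lowest total was 136 RPM, so shares under these limits could only stay the same. The 36 tests chosen after seeing the data kept theirs in 623 of 657 (25 weaker, 4 stronger, 5 turned) and 284 of 303 (16, 3 and 0). Averaging libraries not separated from sampling noise changed no total call. Values are log2 differences or percentage points; causes not named were not tested.

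With 1 mean per event, fewer values entered: always green against always red gave 7.70, fully green against fully red ZmUBQ 4.71, and ZmUBQ against 35S always red -0.96, all short of the threshold; length classes passed in 12 tests in place of 27, shares in 3 in place of 17, and the 24 nt share of green against red parts turned to 0.0484. In pairs, fully green against green parts passed at 0.57, and no other call on a total changed; length classes passed in 15 and shares in 10 of 15 tests that pairs allow, where 13 and 8 passed unpaired. The 22 nt share of red parts against fully red leaves turned to -0.0270 without libraries under 8 M mapped reads and to -0.0525 without red parts of MK016 number 5 and MK025 number 1.

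The dcl1234 total passed as -0.92 over 21 to 24 nt and -1.58 over 21 and 22 nt, because the other lengths were higher in dcl1234, as -2.83 on the minus strand alone and as -1.72 for 21 to 24 nt relative to the other lengths. For the same ratio, green against red parts was 0.56, fully red against always red 0.22 and ZmUBQ against 35S fully green -0.0056, none past the threshold. Always green against fully green turned to -0.60 and ZmUBQ against 35S always red to 0.25. In these comparisons the other lengths moved with the total. On the minus strand alone, ZmUBQ against 35S always red was -0.63 and missed it. As a share of 21 to 24 nt reads, the 22 nt share turned to -3.36 (fully green against fully red 35S), -2.86 (red parts against fully red) and 9.19 (dcl1234), and the 21 nt share of fully green against green parts to -0.762, because the sum in the denominator changed.

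Leaving out an event ended the call for ZmUBQ against 35S always red without MK016 (-0.78), MK042 (-0.89), MK045 (-0.90) and MK054 (-0.64), made one for dcl1234 without MK034 (-0.32), and turned ZmUBQ fully red against always red without MK054 (-0.13). With 1 library left out, always green against always red ranged from 7.54 to 7.94, dcl1234 from -0.30 to -0.0675, ZmUBQ against 35S always red from -1.11 to -0.67, and the promoter difference in the green rise from -0.79 to 0.0612. Ranges that crossed 0 were -0.26 to 0.0185 for 24 nt ZmUBQ fully red against always red, with, among tests chosen after seeing the data, -0.0061 to 0.39 for other lengths and -1.87 to 2.28 for the minus strand share; -0.121 to 0.0277 for the 24 nt share of green against red parts; -0.0185 to 0.189 for the 22 nt share of red parts against fully red; and -0.181 to 0.0803 for the 24 nt share of ZmUBQ against 35S fully green. Adjusted p over the alternatives ran from 0.002 to 0.218 for ZmUBQ against 35S always red, 7.94e-05 to 0.988 for dcl1234, 0.0156 to 0.285 for fully green against green parts, 0.0003 to 0.0670 for green against red parts, 0.00069 to 0.412 for fully red against always red, 0.0171 to 0.214 for always green against always red, 0.00117 to 0.184 for ZmUBQ fully green against fully red and 0.000524 to 0.978 for ZmUBQ against 35S fully green.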
